A study of Mus musculus with 24 samples.

How the data were processed

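Small RNA was sequenced from mouse lung (C57BL/6) after X-ray irradiation of the whole thorax at 15 Gy, or without irradiation, at day 14, day 90 and day 180. The labels give 6 groups of 4 libraries, 24 in all. The labels do not say whether the 4 libraries of a group came from 4 animals, so p-values of single miRNAs measure the spread between these libraries. Per the labels' protocols, total RNA was extracted with Trizol, small RNA was cut from a gel, adaptors were ligated to both ends, and the cDNA was amplified by PCR.

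The authors deposited a table per time point with a count and an RPM value, the count scaled to a common total, for each mature miRNA in each library. The deposited counts are whole numbers that were not normalised, per the file headers and the values. The deposited RPM values divide these counts by a total of 11984009 to 16081430 per library, about 4 times the sum of the counts in the table, and what that total holds is not given in the sources used here. Bowtie2 and the mouse build GRCm38.p6 are named in the submitters' processing notes, with no role and no Bowtie2 version. Whether unique molecular identifiers were used is not given in the sources used here, so counts are not taken as independent molecules. The errors and p-values given for single miRNAs come from the spread between libraries. Every value column was matched to a library by its name.

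The tables hold 1657, 1707 and 1767 mature miRNAs at day 14, 90 and 180, of which 386, 413 and 433 carry names of predicted, unannotated miRNAs. The 3 tables were not made in one way. In the day 14 and day 90 tables, 10 groups of related miRNAs (21 miRNAs, among them miR-199a-3p with miR-199b-3p and miR-486a-5p with miR-486b-5p) have identical counts in all 16 libraries, while in the day 180 table the members of each group differ. The lists count both members of such pairs: miR-486a-5p and miR-486b-5p in the erythroid list, and miR-199a-3p and miR-199b-3p in the fibrosis-promoting and fibroblast lists. Values of single members are therefore uncertain, and so are values of miRNAs with near-identical relatives, such as miR-133a-3p and miR-133b-3p, where the counting could split or share reads. Total counts were 2899300 to 3301198 per library at day 14, 3464742 to 3638984 at day 90 and 2832205 to 3695133 at day 180. The closest pair of libraries of a day differed by a chi-square of 83 (day 14), 75.3 (day 90) and 63.3 (day 180) per degree of freedom, far above the noise of independent reads, so no library was counted as a copy of another. This cannot show whether libraries share an animal.

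Each time point was tested alone with edgeR 4.0.16 (R 4.3.3): features kept by filterByExpr, TMM normalisation, the quasi-likelihood F-test with its legacy fit, and Benjamini-Hochberg adjustment with a threshold of 0.05 and no minimum fold. This left 499, 558 and 552 miRNAs. The SE of a log2 fold change was derived from its size and the F statistic, and is approximate, above all where counts reach 0. Levels are CPM, counts scaled by TMM-adjusted library sizes, computed within a time point. Levels given for controls between time points come from 1 scaling of the 12 control libraries and differ from those within a time point. The difference of the radiation effect between time points, and the controls between time points, were tested in joint fits on the miRNAs shared by the 3 tables (624 and 564 tested). Of 20 miRNA lists, the 17 with at least 3 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares the members of a list with all other miRNAs. Its p-values therefore also rest on the spread across miRNAs and on the correlation used. Unlike camera, fry tests whether the members of a list differ from no change, so its result is not the same call under another setting. Lists are adjusted over the lists of a comparison. Exact permutation tests of 4 against 4 libraries are two-sided and cannot go below p = 0.0286, or below 0.125 within the 4 pairs taken at day 14. Positions of miRNA hairpins are from the GENCODE annotation of GRCm38, the build the submitters name.

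On data simulated from these libraries, the test recovered 57.6%, 58.6% and 29.9% of miRNAs changed 2-fold and 97%, 98% and 87.6% of those changed 4-fold at day 14, 90 and 180 (499, 558 and 552 miRNAs). It made 0, 5 and 2 false calls among unchanged miRNAs there, and none where nothing was changed. The simulation held 99, 99 and 97 miRNAs changed 2-fold and 100, 99 and 97 changed 4-fold, against 0, 2 and 0 calls in the measured data. With so many changed the adjustment is more lenient, so the recovered shares need not hold for the measured data. Effect differences of 4-fold were recovered in 73.5% (day 180 minus 14) and 76% (day 180 minus 90) of 196 miRNAs, among 610 simulated, with 7 false calls among unchanged miRNAs in each, and no change was simulated for day 90 minus 14, which gave 0 calls. A list raised 2-fold, among 494, 544 and 537 miRNAs, had a camera adjusted p of 0.00262, 0.00158 and 0.000658 at day 14, 90 and 180. With an estimated correlation the same list had 0.132, 0.354 and 0.0894, so that test missed a simulated change of this size on all 3 days. The simulated miRNAs were drawn independently, while measured miRNAs can move together. The simulation therefore cannot show which list test is right for the measured data. fry recovered that list at day 14 and day 180 (adjusted p = 0.0489 and 0.0452) and not at day 90 (0.536), and it passed 0 of the measured lists at day 14 and day 180 and 6 at day 90. At day 14 camera also called 1 of the 14 lists that were not raised.

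The design, the lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. The rule names, at each time point, up to 10 miRNAs per direction past the threshold with no overlap between groups and a mean of at least 10 CPM, and the 10 with the smallest p where fewer than 5 pass. It also names miR-208a-3p and its relatives, up to 4 members of each list by smallest p, the 5 most abundant miRNAs, and the 5 with the smallest p for each effect difference. It names 75, 69 and 76 tested miRNAs at day 14, 90 and 180. Values under the alternatives are summarised for a subset of 25, 27 and 33 of these, the text gives values for some of this subset and none outside it, and both choices were made after values were seen. In at least 1 alternative 17, 9 and 19 of all those named change sign, against 4, 1 and 7 of the subset, so in sign the subset is more stable than the whole set. In calls it is less stable: 3, 20 and 25 of all those named gain or lose a call in at least 1 alternative, and 3, 18 and 22 of these belong to the subset. Predicted miRNAs are counted but not named. The miRNAs named for the controls between time points lie outside the rule and were chosen after their values were seen.

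Alternatives were other scalings (RLE size factors, library size alone, upper-quartile), no filter, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, robust dispersion, annotated miRNAs alone, all 24 libraries in one fit, the replicate number as a block, and leaving out each library. The total behind the deposited RPM values as library size, miRNAs with identical counts taken as one, miRNAs with a mean of 50000 counts or more left out, edgeR's newer fit (legacy = FALSE) and voom with library quality weights were chosen after seeing the data. Lists were repeated with RLE size factors, abundant miRNAs left out, identical miRNAs as one, the replicate block and each library left out. The estimated correlation and fry also count among the alternatives of lists and enter their ranges. The labels number the libraries 1 to 4 in every group. At day 14 same-numbered control and irradiated libraries deviated together (correlations of 0.408, 0.172, 0.465 and 0.411, all over 0.1), and 7 of 8 libraries were closest to their own number, so the numbers were taken to pair the libraries there, from the data and not from a label. At day 90 and day 180 the correlations went down to -0.224 and -0.356, so the numbers were not taken as pairs.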

Results

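miRNA abundance was measured by small RNA sequencing in lungs of C57BL/6 mice, an inbred laboratory strain, at day 14, day 90 and day 180 after 15 Gy of X-rays to the thorax, each with unirradiated controls. There were 4 libraries per group. Total counts lay between 2832205 and 3695133 per library, and mean totals of control and irradiated libraries were 3183930 and 3118182 at day 14, 3539644 and 3533538 at day 90, and 3559993 and 3324724 at day 180. The 10 most abundant miRNAs took 27% to 35.2% of the counts. The study's title concerns miR-208a-3p and the phosphatase gene PPP6C in radiation-induced lung injury. The tables hold miRNAs, so PPP6C was not measured here.

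At day 14, miR-34a-5p, a miRNA induced by p53, stood at 21456 ± 4659 CPM in irradiated and 12201 ± 471 CPM in control lungs (SD, n = 4 each), 1.76-fold, with all 4 irradiated libraries above all 4 controls. Its hairpin lies on chromosome 4, 150068454 to 150068555, plus strand, outside other annotated genes (GRCm38). miR-208a-3p, encoded in an intron of the heart myosin gene Myh6 (chromosome 14, 54949060 to 54949142, minus strand), stood at 35.1 ± 26.2 against 5.74 ± 6.53 CPM, with overlapping libraries. miR-342-3p stood at 947 ± 96.8 against 1256 ± 97.4 CPM, miR-92a-1-5p at 12.9 ± 2.44 against 21.7 ± 2.96 CPM and miR-503-3p at 34.5 ± 4.83 against 50.4 ± 8.22 CPM, each below all controls. None of these 5 passed the test.

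The comparison asked which miRNAs differ early after irradiation. edgeR called 0 of 499 miRNAs, with 27 at an unadjusted p under 0.05 where 25 are expected by chance. DESeq2 called 1 miRNA and limma-voom 0. In 12 miRNAs (2.4%) the groups did not overlap, and chance gives 2.86%. For miR-34a-5p the log2 fold change was 0.81 ± 0.16 (SE) with an edgeR adjusted p of 0.328, and the exact permutation p over all splits was 0.0286, the smallest possible. Within the 4 pairs that the replicate numbers make at this day it was higher in 4 of 4, with an exact permutation p of 0.125, the smallest that 4 pairs allow. Counts were 37311 to 40347 in controls and 46931 to 76512 in irradiated lungs. miR-208a-3p had a log2 fold change of 2.59 ± 0.89 (edgeR adjusted p = 0.804, exact permutation p = 0.0571, or 0.25 within the pairs) from counts of 5 to 52 against 14 to 201. For miR-34a-5p the adjusted p was 0.02 with no filter, 0.024 with DESeq2, 0.0325 with all 24 libraries in one fit and 0.00137 without irradiated library 4, in a range of 0.00137 to 0.97 over the alternatives.

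Control library 2 of day 14 held 640 CPM of miR-206-3p, a skeletal muscle miRNA, against a mean of 12.4 CPM in the other 3 controls. It held 731 against 42.9 CPM of miR-205-5p and 3285 against 625 CPM of miR-203-3p, both miRNAs of stratified epithelia. Group means of these miRNAs rest on that library: miR-206-3p stood at 169 ± 314 CPM in controls and 9.72 ± 2.59 CPM in irradiated lungs. miR-206-3p passed with no filter (0.0487, in a range of 0.0487 to 0.989 over the alternatives). miR-744-5p stood at 255 ± 296 CPM in controls and 10.1 ± 4.47 CPM in irradiated lungs (edgeR adjusted p = 0.804, or 0.0201 with no filter, in a range of 0.0201 to 0.97). Its control mean rests on libraries 2 and 4 (590 and 418 CPM), with 4.33 and 8.53 CPM in libraries 1 and 3.

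Among the lists at day 14, the erythroid miRNAs rose (camera adjusted p = 0.00238, or adjusted p = 0.135 with an estimated correlation), with all 7 measured members above 0 and a median log2 fold change of 0.30. Of these, miR-486a-5p and miR-486b-5p have identical counts and are 1 measurement, whose value is the median, and with them taken as one the median was 0.37 (0.00983, in a range of 0.00149 to 0.135). miR-144-3p of that list stood at 1558 ± 480 against 957 ± 421 CPM. miR-208a-3p and its relatives, the miRNAs of the myosin genes, rose as a list (median 1.22, camera adjusted p = 0.047, or adjusted p = 0.626 with an estimated correlation), with 3 of 4 members above 0. No member of either list passed over all miRNAs tested, and 2 of the relatives and 0 of the erythroid list passed when adjusted over the list alone. The call of the relatives was lost without any 1 of 6 libraries (control 1, 3 or 4, irradiated 1, 3 or 4), with adjusted p of 0.0532 to 0.199, and its adjusted p ranged from 0.00403 to 0.626 over the alternatives. With the replicate number as a block, since the numbers pair the libraries at this day, the adjusted p of the relatives was 0.193 and that of the ciliated cell list was 0.0413, down from 0.0666 and in a range of 0.0115 to 0.674. The ciliated list had a median of -0.27 and 4 of 5 members below 0. miR-34c-5p of it stood at 1850 ± 279 against 2304 ± 318 CPM.

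The other lists did not pass at day 14. Their medians and camera adjusted p were -0.20 and 0.957 for p53-regulated, -0.07 and 0.0928 for fibrosis-promoting, -0.05 and 0.62 for fibrosis-restraining, 0.02 and 0.766 for inflammatory, and -0.13 and 0.172 for the proliferation clusters. They were 0.0046 and 0.786 for let-7, 0.05 and 0.559 for the imprinted chromosome 12 cluster, -0.09 and 0.559 for epithelial, 0.08 and 0.786 for smooth muscle, and -0.22 and 0.0928 for fibroblast. They were 0.58 and 0.0928 for striated muscle, -0.10 and 0.62 for myeloid, -0.04 and 0.595 for lymphoid, and -0.13 and 0.495 for neural miRNAs. For the p53-regulated list (mean -0.04) camera ranked upward, and for the inflammatory list (mean 0.05) downward, against the signs of their medians. miR-34a-5p passed when adjusted over the p53-regulated list alone (0.00591). Some lists passed when 1 library was left out: striated muscle (0.0069) and ciliated (0.0115) without control library 2, fibroblast (0.0422) without control library 4, striated muscle (0.00403) and imprinted (0.00589) without irradiated library 2, and ciliated (0.0176) without irradiated library 3. Over all alternatives the adjusted p ranged from 0.00403 to 0.674 for striated muscle, 0.0422 to 0.674 for fibroblast and 0.00589 to 0.983 for imprinted miRNAs.

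At day 90, 2 miRNAs rose in irradiated lungs. miR-133b-3p, a striated muscle miRNA, rose from 1.63 ± 0.755 to 9.24 ± 1.76 CPM (SD, n = 4 each), 5.56-fold. miR-122-3p, from the hairpin of the liver miRNA miR-122, rose from 19.4 ± 5.84 to 60.9 ± 11.6 CPM, 3.13-fold. miR-208a-3p stood at 192 ± 156 CPM against 12 ± 16.6 CPM, with all 4 irradiated libraries above the controls, and did not pass. As a list the striated muscle miRNAs rose by camera, all 8 measured members being above 0, and this call was lost with an estimated correlation (adjusted p = 0.101).

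This comparison asked the same question at day 90. edgeR called 2 of 558 miRNAs, with 71 at an unadjusted p under 0.05 where 27.9 are expected. In 40 miRNAs (7.17%) the groups did not overlap, against 2.86% by chance. miR-133b-3p (chromosome 1, 20682769 to 20682887, plus strand, in an exon of the long non-coding RNA gene Gm28653) had a log2 fold change of 2.48 ± 0.36 (SE). miR-122-3p (chromosome 18, 65248861 to 65248926, plus strand, in an exon of the long non-coding RNA gene AC157910.3) had 1.64 ± 0.26. The adjusted p was 0.0221 for both, in a range over the alternatives of 8.22e-06 to 0.252 for miR-133b-3p and 2.06e-06 to 0.594 for miR-122-3p. DESeq2 called 19 miRNAs and limma-voom 3. miR-208a-3p had a log2 fold change of 4.00 ± 1.21 (edgeR adjusted p = 0.216, exact permutation p = 0.0286, the smallest possible), from counts of 0 to 120 in controls and 168 to 1417 in irradiated lungs. Both calls were lost with all 24 libraries in one fit (0.252 and 0.594) and without any 1 of 4 libraries (control 1, irradiated 1, 2 or 3), and that of miR-122-3p also at a mean of at least 10 CPM (0.0523) and without control 2 or 3 (0.0884 and 0.132), while without control library 4 edgeR called 7 miRNAs (5 higher, 2 lower). Without the 4 libraries named first the adjusted p was 0.0525 to 0.11 for miR-133b-3p and 0.0986 to 0.163 for miR-122-3p. miR-208a-3p passed with no filter (4.51e-05), in a range of 4.51e-05 to 0.456 over its alternatives, and its fold depends on the prior count since controls reached 0 counts.

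**Figure D1:**
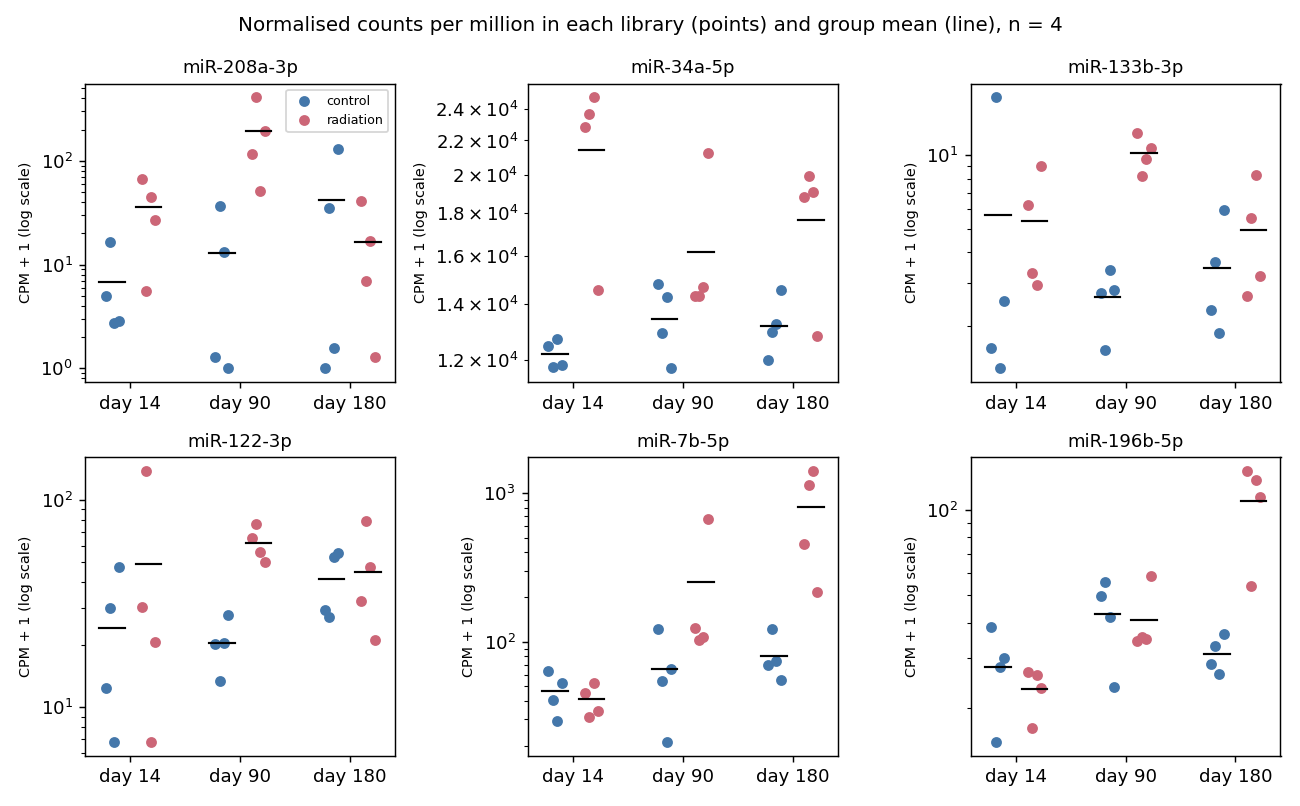
Levels of 6 miRNAs in each library (points, CPM plus 1, log axis) by day, with group means as lines, for control (blue) and irradiated (red) lungs, 4 libraries per group. At day 90 miR-208a-3p lies above the controls in all 4 irradiated libraries with an SD of 156 CPM, while at day 180 the groups overlap.

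Further miRNAs of the muscle list at day 90 had values that did not pass over all miRNAs with edgeR: miR-499-5p stood at 59.3 ± 12.3 against 29.1 ± 8.09 CPM, miR-133a-3p at 322 ± 132 against 115 ± 58.8 CPM and miR-208a-5p at 36.9 ± 30.6 against 5.12 ± 6.85 CPM. miR-208b-3p stood at 32.5 ± 12 against 24.9 ± 7.49 CPM. miR-499-5p passed with DESeq2 (range 0.00728 to 0.394 over the alternatives), miR-133a-3p with DESeq2 and with no filter (0.00167 to 0.432), and miR-208a-5p with no filter (0.00343 to 0.667). Adjusted over the list alone, 6 of 8 muscle members passed. The list's median was 1.44 (camera adjusted p = 2.01e-07, or adjusted p = 0.101 with an estimated correlation). The relatives of miR-208a-3p, whose 4 measured members all belong to the muscle list too, rose with a median of 1.94 (0.00104, or adjusted p = 0.193 with an estimated correlation), and 3 of 4 passed when adjusted over the list alone. The hepatocyte miRNA miR-122-5p stood at 873 ± 183 against 235 ± 141 CPM (edgeR adjusted p = 0.076). It passed with upper-quartile scaling, no filter, DESeq2, limma-voom, the newer edgeR fit and voom library weights. It also passed without control library 4 (0.00163, in a range of 6.77e-06 to 0.41 over the alternatives).

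The imprinted chromosome 12 cluster, a large group of miRNAs expressed from 1 parental chromosome, rose as a list at day 90, with 32 of 33 members above 0 and a median of 0.47 (camera adjusted p = 1.34e-08, or adjusted p = 0.101 with an estimated correlation). No member passed over all miRNAs and 3 passed when adjusted over the list alone. These 3 were miR-136-5p, which stood at 58 ± 20.8 against 22.9 ± 6.48 CPM, miR-376a-3p at 146 ± 36.8 against 63.5 ± 24.9 CPM and miR-541-5p at 38.5 ± 9.36 against 22.9 ± 1.44 CPM. miR-379-5p stood at 530 ± 5.74 against 365 ± 50.1 CPM and did not pass over the list alone (0.067). With DESeq2 all 4 passed over all miRNAs, with ranges of the adjusted p over the alternatives of 0.00557 to 0.394 for miR-136-5p, 0.00961 to 0.394 for miR-376a-3p, 0.0392 to 0.668 for miR-541-5p and 0.00741 to 0.606 for miR-379-5p. miR-136-5p also passed with no filter and with upper-quartile scaling, and miR-376a-3p with no filter, with voom library weights and without control library 4 (0.0218). The ciliated cell miRNAs rose, 6 of 6 above 0 with a median of 0.36 (0.0123, or adjusted p = 0.133 with an estimated correlation). miR-34b-5p stood at 3173 ± 449 against 1711 ± 477 CPM and passed when adjusted over the list alone, and over all miRNAs with DESeq2 and with no filter (0.00369 to 0.394 over the alternatives).

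Lymphoid miRNAs fell at day 90, 5 of 5 below 0 with a median of -0.16 (camera adjusted p = 0.00635, or adjusted p = 0.133 with an estimated correlation), and 2 passed when adjusted over the list alone. miR-150-5p, a miRNA of mature lymphocytes, stood at 13626 ± 2595 against 21100 ± 4756 CPM, and miR-150-3p at 7.12 ± 1.71 against 14 ± 1.32 CPM, which passed over all miRNAs with DESeq2 (0.0164 to 0.466 over the alternatives). The proliferation clusters fell, 10 of 10 below 0 with a median of -0.24 (0.0493, or adjusted p = 0.542 with an estimated correlation), and 0 passed when adjusted over the list alone. That call was lost with RLE size factors (0.0578), without abundant miRNAs (0.0518) and without any 1 of 5 libraries (control 2 or 4, irradiated 1, 3 or 4, with adjusted p of 0.0653 to 0.239), in a range of 0.000678 to 0.542. The lymphoid call was lost without abundant miRNAs (0.0656, in a range of 0.00152 to 0.133), and miR-150-5p passed without control library 4 (0.0317, in a range of 0.00964 to 0.432).

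The other lists did not pass at day 90. Their medians and camera adjusted p were 0.18 and 0.162 for p53-regulated, 0.11 and 0.988 for fibrosis-promoting, 0.10 and 0.194 for fibrosis-restraining, 0.0089 and 0.988 for inflammatory (-0.01 with RLE size factors), and -0.03 and 0.988 for let-7. They were 0.12 and 0.106 for epithelial, 0.06 and 0.909 for smooth muscle, -0.13 and 0.863 for fibroblast, 0.07 and 0.502 for erythroid, 0.33 and 0.929 for myeloid, and -0.20 and 0.863 for neural miRNAs. Camera ranked the fibrosis-promoting list (mean 0.03) downward and the neural list (mean 0.04) upward, against their medians, and the let-7 mean of 0.01 had the other sign from its median. fry passed 6 lists at day 90, the p53-regulated list among them (0.0062) and not the proliferation clusters (0.394). The p53-regulated list shares the miR-34b and miR-34c miRNAs with the ciliated list, so these lists are not separate findings. The epithelial list passed without control library 1 (0.0339) or irradiated library 4 (0.0177), in a range of 0.0177 to 0.542, and the fibrosis-restraining list without irradiated library 4 (0.00972), in a range of 0.00972 to 0.857.

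At day 180, no single miRNA passed. miR-7b-5p, a neural and neuroendocrine miRNA, stood at 807 ± 565 CPM in irradiated and 79.1 ± 28.6 CPM in control lungs (SD, n = 4 each). miR-196b-5p, from the Hoxa cluster, stood at 106 ± 37.2 against 30.2 ± 4.6 CPM, miR-124-3p at 35.8 ± 14.9 against 8.65 ± 3.03 CPM and miR-184-3p at 74.9 ± 42.8 against 15 ± 6.81 CPM, each above all 4 controls. Inflammatory and neural miRNAs rose as lists and the proliferation clusters fell by camera. None of these 3 calls held with an estimated correlation (adjusted p = 0.326 for each) or with fry (0.16, 0.124 and 0.124), and the neural call was lost without irradiated library 1 (0.0647). miR-208a-3p stood at 15.6 ± 17.6 against 41.2 ± 61.3 CPM, with overlapping libraries.

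This comparison asked which miRNAs differ late after irradiation. edgeR called 0 of 552 miRNAs, with 101 at an unadjusted p under 0.05 where 27.6 are expected. DESeq2 called 28 miRNAs (18 higher, 10 lower) and limma-voom 0. In 66 miRNAs (12%) the groups did not overlap, against 2.86% by chance. miR-7b-5p (chromosome 17, 56242988 to 56243098, plus strand) had a log2 fold change of 3.35 ± 0.59 (SE) and miR-196b-5p (chromosome 6, 52230081 to 52230165, minus strand, in an exon of Hoxa9) of 1.81 ± 0.33, both with an edgeR adjusted p of 0.0809. miR-208a-3p had -1.42 ± 1.55 (edgeR adjusted p = 0.658, exact permutation p = 0.971), from counts of 0 to 420 in controls and 1 to 97 in irradiated lungs, and its sign turned without control library 4 (0.40). Irradiated library 1 had the lowest total count (2832205), a median Spearman correlation of 0.914 to the other libraries against 0.94 to 0.962 for those, and without it edgeR called 0 miRNAs. Other counts were 18 with no filter, 32 with all 24 libraries in one fit, 44 with voom library weights, 5 without irradiated library 2 and 3 without irradiated library 4. miR-196b-5p (0.0191) and miR-184-3p (0.0419) passed without irradiated library 2, and miR-7b-5p (0.0209) and miR-124-3p (0.0296) without irradiated library 4. With all libraries kept, miR-7b-5p, miR-196b-5p and miR-184-3p passed with no filter, DESeq2, voom library weights and all 24 libraries in one fit. miR-124-3p passed with all but the last of these. The adjusted p over the alternatives ranged from 7.89e-08 to 0.32 for miR-7b-5p, 4.68e-05 to 0.453 for miR-196b-5p and 0.000495 to 0.453 for miR-184-3p and miR-124-3p.

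Inflammatory miRNAs at day 180 had 11 of 12 members above 0 and a median of 1.05 (camera adjusted p = 0.000474, or adjusted p = 0.326 with an estimated correlation), and 7 passed when adjusted over the list alone. miR-21a-3p stood at 352 ± 271 against 76 ± 29.2 CPM, miR-155-5p, a miRNA of activated leukocytes, at 1039 ± 676 against 455 ± 94.2 CPM and miR-21a-5p at 25138 ± 2963 against 18553 ± 1220 CPM. The neural list had 5 of 6 members above 0 and a median of 1.196 (0.00134, or adjusted p = 0.326 with an estimated correlation), and 4 passed when adjusted over the list alone, but the list did not pass without irradiated library 1 (median 0.64, adjusted p = 0.0647, in a range of 0.000358 to 0.326). The imprinted chromosome 12 cluster rose again, 32 of 33 above 0 with a median of 0.65 (0.000474, or adjusted p = 0.326 with an estimated correlation) and 0 passing when adjusted over the list alone. miR-127-3p of it stood at 1592 ± 953 against 791 ± 74.6 CPM, with 2999 CPM in irradiated library 1 and 1002 to 1362 CPM in the other irradiated libraries. Over all miRNAs, miR-21a-3p passed with no filter, DESeq2 and voom library weights (0.00337 to 0.481 over the alternatives), miR-21a-5p with voom library weights and all 24 libraries in one fit (0.0152 to 0.585), and miR-155-5p (0.0371 to 0.496) and miR-127-3p (0.0287 to 0.496) with that one fit.

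The proliferation clusters fell at day 180, 8 of 9 below 0 with a median of -0.52 (camera adjusted p = 0.00133, or adjusted p = 0.326 with an estimated correlation). miR-19b-3p stood at 234 ± 34.6 against 373 ± 32.4 CPM. Erythroid miRNAs fell (median -0.26, 0.0145, or adjusted p = 0.326 with an estimated correlation), with 5 of 7 below 0, and fibrosis-restraining miRNAs fell (median -0.35, 0.0186, or adjusted p = 0.326 with an estimated correlation), with 9 of 12 below 0. Of these 3 lists 0 members passed when adjusted over the list alone. Without irradiated library 4 neither the erythroid nor the fibrosis-restraining list passed (both 0.099), and the erythroid median was -0.02 both there and without irradiated library 3 (0.0818). The erythroid median is the value of miR-486b-5p, whose counts are uncertain at this day, and with that miRNA and miR-486a-5p taken as one it was -0.38 (0.0274). The adjusted p ranged over the alternatives from 0.000241 to 0.326 for the erythroid and 0.00309 to 0.326 for the fibrosis-restraining list. miR-144-3p stood at 1264 ± 611 against 2262 ± 607 CPM and miR-338-3p at 389 ± 98.1 against 587 ± 69.9 CPM. Over all miRNAs, miR-19b-3p passed with DESeq2 and voom library weights (0.0202 to 0.496 over the alternatives) and miR-144-3p with these weights (0.0192 to 0.496). The median of all miRNAs tested at this day was 0.126 (0.088 to 0.149 over the other scalings), so medians near that value are no shift relative to the rest.

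The other lists did not pass at day 180. Their medians and camera adjusted p were -1.24 and 0.515 for the relatives of miR-208a-3p, -0.37 and 0.0874 for p53-regulated, 0.41 and 0.18 for fibrosis-promoting, 0.10 and 0.968 for let-7, and -0.08 and 0.136 for epithelial. They were -0.16 and 0.136 for ciliated, -0.06 and 0.504 for smooth muscle, 0.12 and 0.566 for fibroblast, -1 and 0.595 for striated muscle, 0.32 and 0.317 for myeloid, and -0.09 and 0.566 for lymphoid miRNAs. The striated muscle and relatives' medians turned positive without control library 4 (0.24 and 0.32), and the p53-regulated list passed without abundant miRNAs (0.0223), control library 1 (0.0372) or irradiated library 3 (0.0074), in a range of 0.0074 to 0.483. The ciliated list, which shares the miR-34b and miR-34c miRNAs with the p53-regulated list, passed without control library 1 (0.0372) or irradiated library 3 (0.0382), in a range of 0.0372 to 0.558. The fibrosis-promoting list passed without irradiated library 1 (0.0206), in a range of 0.0206 to 0.637. The fibroblast mean of -0.17 and the lymphoid mean of 0.09 had the other sign from their medians. miR-145a-5p of the smooth muscle list stood at 3512 ± 861 against 6361 ± 1898 CPM and passed when adjusted over the list alone.

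**Figure D2:**
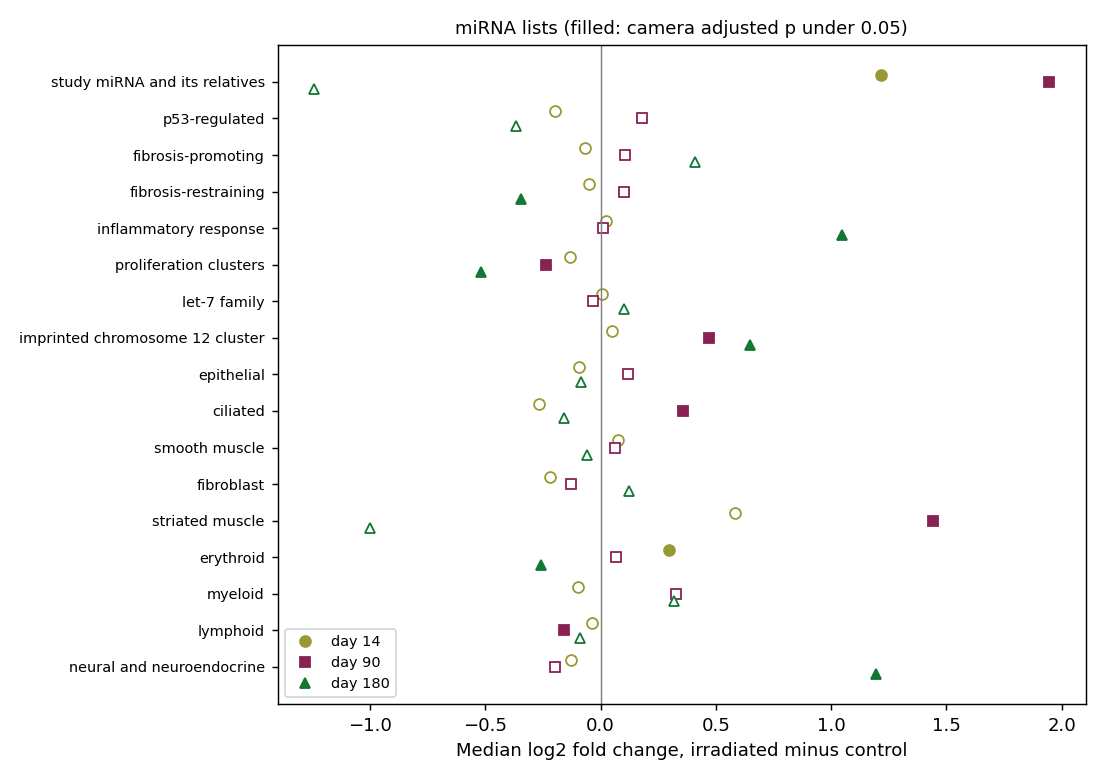
Median log2 fold change (irradiated minus control) of the 17 tested miRNA lists at day 14 (circles), day 90 (squares) and day 180 (triangles), filled where the camera adjusted p was under 0.05. The relatives of miR-208a-3p and the striated muscle miRNAs have medians of 1.94 and 1.44 at day 90 and -1.24 and -1 at day 180, and no filled point passes with an estimated correlation.

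Of the lists with fewer than 3 measured members, the hypoxia miRNA miR-210-3p stood at 20.3 ± 3.2 against 23.9 ± 9.44 CPM at day 14, 23.6 ± 4.5 against 25.8 ± 10.3 CPM at day 90 and 34.3 ± 35 against 19.1 ± 5.15 CPM at day 180. The last irradiated mean rests on library 4, with 86.49 CPM against a mean of 16.9 CPM in the other irradiated libraries. The endothelial miRNA miR-126a-3p stood at 40649 ± 2443 against 40375 ± 4375 CPM, 31561 ± 2054 against 32549 ± 2755 CPM and 34483 ± 8306 against 31965 ± 2411 CPM. Its counts at day 180 were nearly equal in all 8 libraries (111905 to 113233), so that its CPM there follows the library total, with 46738 CPM in irradiated library 1, which had the lowest total (2832205), and the day 180 values need not measure an endothelial level. miR-122-5p of hepatocytes stood at 714 ± 188 against 744 ± 140 CPM at day 180. At day 14 it stood at 718 ± 928 against 367 ± 272 CPM, with 2097 CPM in irradiated library 2 against a mean of 258.5 CPM in the other irradiated libraries. None of these differences passed the test.

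Whether the radiation effect differed between time points was tested directly. For miR-208a-3p the effect at day 180 was lower than at day 90 by a log2 difference of -5.44 ± 2.04 (SE, edgeR adjusted p = 0.272), and the differences were 1.45 ± 1.99 for day 90 minus 14 (0.996) and -3.99 ± 2.03 for day 180 minus 14 (0.438). miR-196b-5p had 2.07 ± 0.45 for day 180 minus 14 (0.0956) and 1.85 ± 0.45 for day 180 minus 90 (0.12), and miR-144-3p had -2.34 ± 0.58 for day 180 minus 90 (0.12). edgeR called 0 of 624 miRNAs in each of the 3 contrasts, with 28, 71 and 91 at an unadjusted p under 0.05 (31.2 expected). DESeq2 called 1 (miR-206-3p), 3 (miR-196b-5p, miR-7b-5p and miR-206-3p) and 2 (miR-32-5p and miR-196b-5p). The miR-206-3p calls subtract the day 14 effect, where control library 2 held 640 CPM against a mean of 12.4 CPM in the other controls. Leaving out 1 library, the edgeR log2 difference of miR-206-3p for day 180 minus 14 ranged from 1.333 to 5.43. By camera 4, 6 and 9 lists differed, and 0 with an estimated correlation (smallest adjusted p = 0.0505, 0.16 and 0.101), while fry passed 0, 0 and 8 of the 17 lists. Leaving out 1 library gave 0 calls for day 90 minus 14. For day 180 minus 14 it gave 18 without irradiated library 2 of day 180, 2 without irradiated library 1 of day 180 or irradiated library 4 of day 90, and 1 without irradiated library 4 or control library 4 of day 180 or control library 2 of day 14. For day 180 minus 90 it gave 10, 5 and 1 without irradiated library 1, 2 or 4 of day 180, 1 without control library 4 of day 180 and 3 without control library 4 of day 90.

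Controls also differed between the tables. miR-181d-5p fell from 522 ± 40 CPM at day 14 to 294 ± 15.8 at day 90 and 229 ± 31.6 at day 180, and miR-126a-3p fell from 44700 ± 5567 to 30465 ± 1739 and 30559 ± 2214 CPM. The counts of miR-126a-3p in control and irradiated libraries lay between 113216 and 136157 at day 14, 111657 and 119208 at day 90, and 111905 and 113233 at day 180, and the day 180 counts are nearly equal whatever the library total, so its CPM at day 180 follows that total. miR-29b-3p, a miRNA that targets collagen transcripts, rose from 1816 ± 293 CPM at day 14 to 4300 ± 572 at day 180. edgeR called 20 of 564 miRNAs at day 90 against day 14 (6 higher, 14 lower), 49 at day 180 against day 14 (14 higher, 35 lower) and 0 at day 180 against day 90, with 99 at an unadjusted p under 0.05 in the last. Age, table and any sequencing batch change together here and cannot be told apart. Calls for day 90 against day 14 fell to 1 and 0 without control library 2 or 4 of day 14, where miR-126a-3p and miR-181d-5p did not pass (0.0561 to 0.0623, in ranges of 0.00294 to 0.0623 and 0.00979 to 0.0623 over the alternatives), and those for day 180 against day 14 fell to 15 and 19. Without control library 3 of day 14 the calls were 11 and 27. For day 90 against day 14 they were 10, 5 and 9 without control library 1, 2 or 3 of day 90, and 8, 9 and 11 without control library 1, 2 or 3 of day 180, where day 180 against day 14 gave 24, 20 and 23. For day 180 against day 90 there were 2, 1 and 3 calls without control library 1, 3 or 4 of day 14, 4 without control library 4 of day 90, and 1 and 3 without control library 1 or 4 of day 180.

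**Figure D3:**
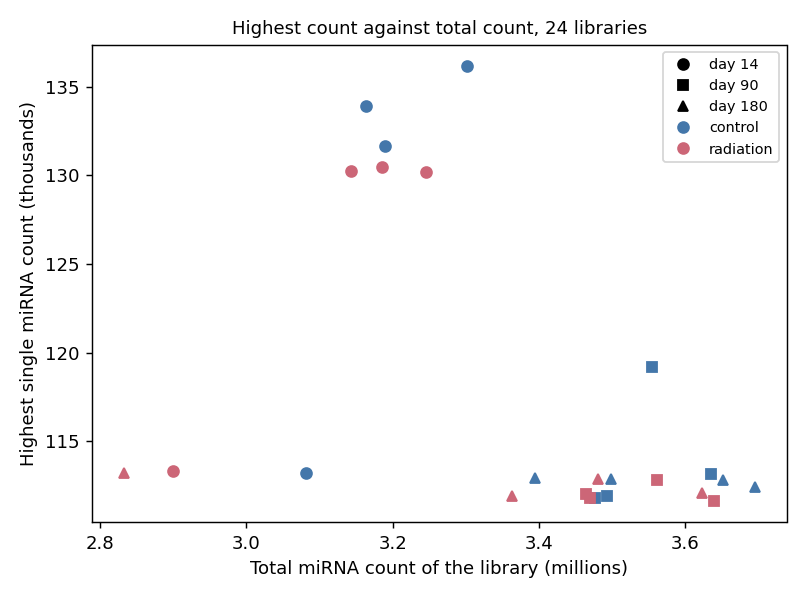
Count of the most abundant single miRNA against the total miRNA count of each of the 24 libraries, by day (symbol) and group (colour), with totals (horizontal) and single counts (vertical) in counts, scaled as the axis labels say. At day 180 the highest counts lie between 111905 and 113233 although totals run from 2832205 to 3695133.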

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

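The tests of muscle tissue, of scaling, of miR-208a-3p beyond the other muscle miRNAs and of a count ceiling were chosen after the result was seen, as was the slope used with the miR-208a-3p ratio, and the effect differences of lists use lists fixed before.

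Muscle miRNAs were higher in irradiated lungs at day 90, where miR-208a-3p and miR-133b-3p stood at 192 and 9.24 CPM against 12 and 1.63 CPM. Over the 24 libraries, centred on their groups, miR-208a-3p followed the mean of miR-1a-3p and miR-133a-3p (Pearson r = 0.924, Spearman rho = 0.93, permutation p = 1e-05, the smallest the resamples can give, adjusted p = 3e-05 over 3 relations, r = 0.911 without the 2 farthest libraries), while miR-122-5p and miR-150-5p did not (r = -0.212 and 0.083, permutation p = 0.356 and 0.733), which is consistent with varying amounts of striated muscle tissue in the samples. A scaling difference would move all miRNAs alike, while the list's median log2 fold change lay 1.467 above that of all tested miRNAs (SE of the 8 members 0.416, lowest member 0.382). Camera had already called this list against all other miRNAs, so the value restates that call and adds no support. The 8 members are not independent of each other. The ratio of miR-208a-3p to those 2 miRNAs was higher in irradiated lungs by 3.792 log2 units (exact permutation p = 0.0286, n = 4 each), which met the bound set for a rise of miR-208a-3p of its own, and the reading was changed to undecided by a slope added after these values were seen: miR-208a-3p moved 2.681 ± 0.269 (SE) log2 units per unit of muscle miRNAs within groups, so the muscle difference of 1.46 alone gives 3.901 of the 5.247 observed and leaves 1.346 ± 0.774. The 5.247 is a difference of mean log2 CPM, with control counts down to 0, and is larger than the fitted log2 fold change given for day 90. The remainder thus depends on how the lowest counts are handled. A rise of miR-208a-3p of its own and one with muscle tissue therefore cannot be told apart, and whether radiation or dissection changed the muscle content was not tested.

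Irradiated library 1 of day 180 stood apart from the other 7, with 2832205 counts, 1023 detected miRNAs and 0.759% of counts in predicted miRNAs, against 0.387% on average in the other irradiated libraries (gap over range 0.881). Lower depth is argued against: after thinning to 2830143 counts its median Spearman correlation was 0.913 against 0.939 to 0.96. GC content stays open, with rho = 0.113 across 442 miRNAs against up to 0.118 in the others. So does a stronger form of the shared response, since its differences correlated with those of the other irradiated libraries at 0.116 (0.048 to 0.196 over the control splits) against 0.188 to 0.385 for these, across miRNAs, which are not independent replicates.

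The highest counts of single miRNAs, those of miR-126a-3p, were nearly equal at day 180 (111905 to 113233). The 10 most abundant miRNAs varied less as counts than as CPM there (ratio of the coefficients of variation 0.43), which is consistent with a ceiling on the count. At day 14 (1.37) the values argue against one shared by all libraries. Highest counts there were 113216 and 113325 in control and irradiated library 1 and 130190 to 136157 in the others. At day 90 totals varied too little (coefficient of variation 2.03%) for the ratio (0.938) to decide. Highest counts there were 111657 to 113133 in all libraries but control library 3 (119208), close to those of day 180. The lower CPM of miR-126a-3p in day 90 and day 180 controls and its day 180 values therefore need not reflect endothelial levels. No biological explanation was tested.

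Of 188 groups of 4 libraries, 17 held a library far from the other 3, measured as the gap to the nearest library over the range. The measure is also high where the other 3 nearly coincide and the distance is small. This holds for miR-379-5p at day 90 (538.5 against a mean of 527.1 CPM) and miR-132-5p at day 180 (15.15 against 12.02 CPM). The nominal rate would give 9.4. Most groups belong to the subset of miRNAs chosen after values were seen, and they share libraries, so 17 against 9.4 shows no excess. At day 14 the outlying values were those of miR-206-3p (0.983), miR-205-5p (0.956), miR-203-3p (0.929) and miR-208a-3p (0.831), all in control library 2, and let-7d-3p (0.863) and miR-122-5p (0.862) in irradiated library 2. At day 90 they were miR-122-5p (0.899) and miR-376a-3p (0.886) in control library 4, miR-379-5p (0.852) in irradiated library 4 and miR-210-3p (0.841) in irradiated library 2. At day 180 they were the share of counts in predicted miRNAs (0.881) and miR-409-3p (0.968) in irradiated library 1, miR-132-5p (0.967) in control library 3, miR-155-5p (0.875) in control library 4, and miR-210-3p (0.877), miR-210-5p (0.858) and miR-34a-5p (0.842) in irradiated library 4.

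The radiation effect on lists differed between time points by camera, with the adjusted p first and that with an estimated correlation after it. For day 90 minus 14 it was higher for the imprinted chromosome 12 cluster (5.55e-05, 0.188), ciliated (0.000108, 0.0505), striated muscle (0.000535, 0.188) and epithelial miRNAs (0.0228, 0.14). Control library 2 of day 14 was outlying in miR-206-3p of the striated muscle list and in miR-205-5p and miR-203-3p of the epithelial list. The differences of lists between time points were not repeated with a library left out, so how far they rest on that library was not tested. For day 180 minus 14 it was higher for inflammatory (0.000143, 0.16), imprinted (0.000262, 0.283) and neural miRNAs (0.0146, 0.283), and lower for erythroid (0.000538, 0.16), p53-regulated (0.0146, 0.16) and fibrosis-restraining miRNAs (0.0477, 0.283). For day 180 minus 90 it was higher for inflammatory (0.000231, 0.101) and neural miRNAs (0.0149, 0.195). It was lower there for striated muscle (0.000231, 0.101), the relatives of miR-208a-3p (0.00165, 0.101), fibrosis-restraining (0.00165, 0.101), ciliated (0.00165, 0.101), erythroid (0.00223, 0.109), p53-regulated (0.0087, 0.101) and epithelial miRNAs (0.0238, 0.101). The ciliated and p53-regulated lists share the miR-34b and miR-34c miRNAs.

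At day 90 only the real split of 35 gave 2 calls (1 of 35, highest other 1), which argues against chance by a margin of 1 call, while the count fell to 0 without any 1 of 4 libraries and with all 24 libraries in one fit. Chance is not excluded for the 6 lists of day 90 (2 of 35, highest other 6), the 2 of day 14 (15 of 35, highest other 7) or the 6 of day 180 (6 of 35, highest other 8). A count of 0 is matched by every split, so the splits test nothing for the single miRNAs at day 14 and day 180 (35 of 35, highest other 4 and 2), for each effect difference (100 of 100 drawn, highest other 4, 9 and 7) or for controls at day 180 against 90 (35 of 35, highest other 2). Of the day 14 splits, the 8 that part all pairs gave up to 3 calls and 7 lists, the others up to 4 and 4. For controls, the 20 calls at day 90 against 14 (1 of 35, highest other 3) and the 49 at day 180 against 14 (1 of 35, highest other 0) argue against chance.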

How the results depend on the processing

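The alternatives with the authors' total as library size, identical miRNAs as one, abundant miRNAs left out, the newer edgeR fit and voom with library weights, and the choice of miRNAs given for controls, were chosen after seeing the data. Of the values under an alternative for the subset of single miRNAs, which holds those given in the text and was chosen after values were seen, 2494 kept direction and side of the threshold, 124 passed where they had not, 27 no longer passed and 27 changed sign. For lists these were 607, 17, 43 and 44. The list values include those with the estimated correlation and with fry, so a change under fry is not a camera call gained or lost. Of the counts, 174 stayed within 1.5 times, 40 were higher and 35 lower. 5 values without an adjusted p, over the lists and all miRNAs the rule names, were left out. Where a call or sign changed, the cause was not tested. Whether depth limits the miRNAs with few counts was not tested.

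With no filter edgeR called 7 (4 higher, 3 lower), 18 (16, 2) and 18 (17, 1) miRNAs at day 14, 90 and 180, and miR-208a-3p at day 90 (3.977). DESeq2 called 1, 19 (15, 4) and 28 (18, 10), and 1, 3 and 2 for the effect differences in the order of the report. All 24 libraries in one fit gave 1, 0 and 32 (22, 10). At day 90 upper-quartile scaling and the newer edgeR fit gave 5 each, voom library weights 6, and a mean of at least 10 CPM 0, where miR-133b-3p was not tested. At day 180 the newer fit gave 3 and voom library weights 44 (22, 22). Of the lists, 0 passed with an estimated correlation at each day and 0 with fry at day 14 and 180. With identical miRNAs as one, 2 were called in controls at day 180 against 90.

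With the replicate number as a block, which pairs the libraries at day 14 alone, day 14 changed as given in the report and in no other call given here. At day 90 and 180, where the numbers are not pairs and 3 and 0 of 8 libraries were closest to their own number, calls went from 2 to 0 at day 90 and stayed at 0 at day 180, and the proliferation clusters of day 90 did not pass (0.0527). The block gave 7 and 25 calls in controls at day 90 and 180 against day 14. Signs turned under it for the medians of inflammatory (-0.0036) and erythroid (-0.0239) miRNAs at day 90, and at day 180 for the relatives (0.1909), fibroblast (-0.1035), striated muscle (0.0649), miR-208a-3p (0.3168) and miR-208a-5p (0.3413).

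Signs also turned under other settings, for inflammatory at day 90 with RLE (-0.0103) and without abundant miRNAs (-0.0864), lymphoid at day 180 without these (0.0285), and fibroblast with identical miRNAs as one at day 90 (0.1138) and day 180 (-0.0444). At day 180 miR-208a-3p was at 0.4304 with voom, weighted or not, miR-208a-5p at 0.121 and, weighted, 0.6341, and with weights miR-126a-3p was at -0.0693 and miR-122-5p at 0.1022. At day 14 miR-126a-3p was at -0.0236 with the authors' total and -0.012 with weights.

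Leaving out 1 library gave 0 to 1, 0 to 7 and 0 to 5 calls and 1 to 4, 5 to 7 and 4 to 8 lists at day 14, 90 and 180. It gave 0 to 0, 0 to 18 and 0 to 10 effect differences, and 0 to 25, 15 to 49 and 0 to 4 calls in controls. miR-208a-3p ranged from 2.132 to 3.794, 3.295 to 5.524 and -2.47 to 0.3951, and its effect differences from 0.2379 to 2.94, -5.061 to -2.076 and -6.862 to -3.464. These ranges crossed 0 at day 14: let-7 -0.0408 to 0.1101, myeloid -0.2399 to 0.1697, neural -0.1695 to 0.0391, inflammatory -0.026 to 0.1317, lymphoid -0.1943 to 0.0802, fibrosis-restraining -0.0745 to 0.0092, smooth muscle -0.0331 to 0.1578, miR-210-3p -0.3789 to 0.068, miR-126a-3p -0.0322 to 0.0802, miR-122-3p -0.3463 to 1.672 and miR-122-5p -0.5071 to 1.62. At day 90 they were inflammatory -0.0516 to 0.0966, neural -0.3589 to 0.207, erythroid -0.1061 to 0.268, smooth muscle -0.0145 to 0.106, fibroblast -0.2363 to 0.156, fibrosis-promoting -0.0184 to 0.1184 and miR-210-3p -0.3263 to 0.0568. At day 180 they were smooth muscle -0.4006 to 0.0551, the relatives -1.618 to 0.3188, striated muscle -1 to 0.2426, let-7 -0.1483 to 0.1906, fibroblast -0.2299 to 0.3883, lymphoid -0.2043 to 0.0007, miR-208a-5p -1.841 to 0.7434, miR-126a-3p -0.0828 to 0.1942, miR-122-3p -0.314 to 0.3754, miR-122-5p -0.2071 to 0.1171, miR-210-5p -0.1878 to 1.507 and miR-210-3p -0.1603 to 1.093.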

Other observations

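No new test was run for this part, and its miRNAs, which did not pass over all miRNAs tested with edgeR, were picked from those the rule names after their values were seen. At day 90 miR-144-3p, an erythroid miRNA, stood at 3074 ± 1528 CPM in irradiated and 1092 ± 507 CPM in control lungs (SD, n = 4 each), and the epithelial miR-141-3p at 3765 ± 867 against 2301 ± 483 CPM, each above all 4 controls (edgeR adjusted p = 0.156 and 0.17). Neither the erythroid nor the epithelial list passed at this day by camera. miR-144-5p, from the same hairpin as miR-144-3p, and the erythroid miR-451a overlapped between the groups, so miR-144-3p does not stand for its list. miR-29b-3p, which targets collagen transcripts, stood at 3679 ± 725 against 2337 ± 673 CPM, and miR-25-3p of the proliferation clusters at 492 ± 48.9 against 859 ± 377 CPM. miR-466h-3p stood at 6.49 ± 0.925 against 15.3 ± 3.51 CPM, below all controls. Over all miRNAs, miR-144-3p passed with no filter and DESeq2 (0.000153 to 0.432 over the alternatives), miR-141-3p with no filter (0.0321 to 0.432), and miR-466h-3p with DESeq2, the newer edgeR fit, voom library weights and without control library 4 (0.00354 to 0.309).

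At day 180 miR-196a-5p, a close relative of miR-196b-5p, stood at 27.2 ± 10.5 against 9.14 ± 2.11 CPM, and miR-7a-5p, a close relative of miR-7b-5p, at 1763 ± 1007 against 826 ± 34.4 CPM, each above all 4 controls. The irradiated mean of miR-7a-5p leans on library 1 (3188 CPM), while library 2 (887.2 CPM) lay close to the highest control (864.9 CPM). miR-26b-5p stood at 9180 ± 1653 against 13865 ± 807 CPM and miR-672-3p at 4.93 ± 0.998 against 13.7 ± 2.8 CPM, each below all controls. The edgeR adjusted p was 0.105, 0.25, 0.163 and 0.0997 in that order. miR-196a-5p passed with DESeq2 and voom library weights (0.00132 to 0.453 over the alternatives), miR-7a-5p with all 24 libraries in one fit (0.0276 to 0.481), miR-26b-5p with all 3 of these settings (0.0192 to 0.453), and miR-672-3p with these and the newer edgeR fit (0.0013 to 0.453). Counts of such close relatives are uncertain where reads could not be assigned to one of them.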
